A study of Rattus norvegicus with 15 samples.

How the data were processed

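MicroRNAs (miRNAs) were measured in hearts of male Sprague-Dawley rats on 15 one-colour arrays, 5 per group. Per the labels, the groups were vehicle-treated controls, rats made diabetic with intravenous streptozotocin at 60 mg/kg (plasma glucose above 300 mg/dL, here DM), and diabetic rats that were also fasted for 24 h and given intraperitoneal insulin at 0.5 IU/kg (here GF, for glucose fluctuation). Per the labels, total RNA was extracted with a column kit and 100 ng was labelled with Cy3. GF replicates are numbered 1, 2, 4, 5 and 6 here, as in the labels. The labels do not say that each array held a separate animal, so the p-values measure the spread between the deposited samples, which may be technical in part.

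Per the file headers, the arrays were read with Agilent Feature Extraction 9.5.3.1, a version that the submitters' processing notes also give. The deposited array files hold signal intensity per spot, background-subtracted and not scaled between arrays, and a total gene signal, also an intensity, summed over the probes of a miRNA. The authors' deposited table of filtered miRNAs holds log2 values. Those log2 values were recomputed from the array files as the log2 total gene signal, with values under 1 set to 1, minus the mean of the 5 control arrays, with no scaling between arrays. The largest difference from the deposited values was 2.05e-06. Per the file headers, the authors kept miRNAs with a raw value of at least 25 in at least 50% of the samples of 1 group. That filter, recomputed from the array files, gave the same 149 miRNAs. The authors' deposited tables of comparisons hold a p-value per miRNA and log2 fold changes; per the file headers the p-value came from an uncorrected test of 3 groups, followed by a post-hoc test of pairs. The software used for these tables is not given in the sources used here.

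Each array had 7953 spots, of which 7000 reported 350 rat miRNAs through 938 probes. A probe was repeated on 5 to 20 spots, and a miRNA had 1 to 4 probes. No spot was saturated (0 over all arrays). From 166 to 190 miRNAs per array were detected by the scanner software, and the 75th percentile of the signal per array ran from 1749 to 3422. The number of arrays limits the precision of every value below.

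Spots flagged by the software were dropped (153 to 294 per array). The gProcessedSignal of each array was scaled to its 75th percentile over the 254 probes well above background on all 15 arrays, where a probe counted as well above background when more than 0.5 of its spots did. Signals under a floor of 4.31 on the log2 scale (19.8) were set to the floor, which is the median over arrays of the lowest scaled signal among probes above background. Spots were averaged per probe, and the brightest probe stood for each miRNA. A miRNA was tested when its probe was well above background on at least 3 of 5 arrays of 1 group; 165 miRNAs were tested and 185 were not. Differences between groups were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Lists of miRNAs fixed before the data were examined were tested with camera of limma at its preset correlation of 0.01, against the other tested miRNAs, when at least 3 members were tested. Single measures of array quality were compared with exact permutation tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

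The arrays were compared in pairs before averaging. For each of the 105 pairs, a reduced chi-square over 156 miRNAs set the differences against the error the scanner software states. In 5 pairs it was under 1, from 0.233 to 0.599, and in the other 100 pairs it ran from 1.09 to 9.42. All 5 pairs joined 2 arrays of 1 group on different slides: control replicates 1 and 3, DM replicates 2 and 4, DM replicates 3 and 5, GF replicates 1 and 5, and GF replicates 2 and 4. The arrays of each pair were averaged and counted once, which left 10 distinct samples: 4 control, 3 DM and 3 GF. Simulated arrays that differed by the stated error alone gave values from 0.726 to 1.27. The 5 close pairs all lay below that range, so the stated error exceeded the differences within them. The range therefore does not show which further arrays repeat a sample. The limit of 1 is a choice made after the data were seen, and 4 further pairs within that range, from 1.09 to 1.19, were kept apart. They join DM replicate 1 to DM replicates 2 and 4 and control replicate 4 to control replicates 1 and 3. Merging them too, an alternative added after the data were seen, leaves 8 samples: 3 control, 2 DM and 3 GF. The planned fit of 15 arrays treats the pairs as independent. The count of each contrast is therefore given from that fit and from the 10 distinct samples, and means with SD are over distinct samples. Counts under some alternatives, such as slide or replicate number as a block, are from the 15 arrays alone.

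The miRNAs named were chosen by a rule written before the data were examined: per contrast, up to 12 with the largest rise and up to 12 with the largest fall among those past the threshold, the 6 with the smallest p where fewer than 6 passed, members of each list with the smallest p, miR-200c and miR-141, and miRNAs that separate the deposited comparison tables from the calls here. The rule allowed up to 4 members per list; 2 were taken for GF against control and 1 for the other contrasts, a limit set later to keep the text short. Any other miRNA named is said to be chosen after its values were seen.

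The alternatives fixed before the data were examined were other scalings (75th percentile over all probes, quantile, none), another background correction (normexp with offset 50), other summaries of a miRNA (mean of its probes, total gene signal), the authors' deposited values, other filters, slide or replicate number as a block, each slide alone, only the 2 groups compared, another variance model, the authors' kind of test, and leaving out each replicate. The normexp correction was planned on the mean spot signal, which the array files used here lack, and was run on the median spot signal. The distinct samples, the pairs as a random block, and a scaling to 4 bright control spots named hur were added after the data were seen. List tests with no scaling or with 75th percentile over all probes, and adjustment of members over their list alone, were not planned. The whole fit was tested on simulated data in which 40 of 165 miRNAs were changed, in 50 simulations. With 15 arrays it recovered 88.8% of changes of 0.5 and 97% of changes of 1 on the log2 scale, and 4.35% of its calls were unchanged miRNAs. With 10 distinct samples it recovered 76.5% and 95.7%, and 3.37% of its calls were unchanged. A list shifted by 0.5 was called in 100% of simulations, and 0.143% of unchanged lists were called. The simulated miRNAs and arrays were independent of each other, with a spread taken from the 15 arrays. In the data the correlation within the close pairs was estimated at 0.83, and within the tested lists at 0.078 to 0.93. The simulated shares of recovered changes and of false calls therefore need not hold for these data. The close pairs narrow the spread that was used, so recovery with 10 distinct samples may be overstated.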

Results

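The series asked how the miRNA profile of the rat heart in diabetes with swings of plasma glucose differs from that in diabetes with steadily high glucose. Expression was measured on 15 arrays: 5 of vehicle-treated control hearts, 5 of hearts from streptozotocin-diabetic rats (DM) and 5 of hearts from diabetic rats that were also fasted and given insulin (GF). Streptozotocin destroys the insulin-producing cells of the pancreas. Between 166 and 190 of 350 miRNAs were detected per array, and 165 were tested. In 5 cases, 2 arrays of 1 group differed by less than the stated measurement error, with reduced chi-squares of 0.233 to 0.599, and each such pair was counted as 1 sample, which left n = 4 control, 3 DM and 3 GF. The fit of all 15 arrays, fixed before the data were examined, takes those arrays as independent. The value over the 10 distinct samples therefore stands beside the count of each contrast and decides the wording. The words rose and fell are used for single miRNAs past the threshold in both fits.

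The brightness of the arrays entered every comparison with GF. The 75th percentile of the signal was 2780 ± 529 (SD, n = 3) in GF, 2027 ± 256 (SD, n = 3) in DM and 2205 ± 261 (SD, n = 4) in control samples. GF exceeded control by 575, with a two-sided exact permutation p of 0.171 (adjusted p = 0.48), and the difference was 835 within slide 1 and 437 within slide 2. GF exceeded DM by 753 (exact permutation p = 0.2; the smallest that 3 against 3 samples allow is 0.1). The median of the tested miRNAs in GF minus control was 0.27 on the log2 scale with no scaling between arrays and -0.052 after the scaling used here. Differences below are relative to the scaled signal.

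The comparison of GF with control hearts asked which miRNAs differ in diabetes with glucose fluctuation. Only GF rats were fasted and given insulin, so in either comparison with GF these cannot be told apart from swings of glucose. The miR-200 family pair miR-200c and miR-141 rose. The signal of miR-200c was 7.87 ± 0.23 (SD, n = 3) on the log2 scale in GF and 5.29 ± 0.71 (SD, n = 4) in control hearts, a 5.97-fold difference over distinct samples (log2 2.58, limma adjusted p = 0.0194); with the normexp background correction the log2 difference was 1.43. Over 15 arrays it was 2.65 ± 0.43 (SE, adjusted p = 0.00052). The signal of miR-141 was 6.96 ± 0.23 (SD, n = 3) in GF hearts. It lay at the floor of 4.31 in 3 of the 4 distinct control samples and at 5.25 in the other, so the size of its difference depends on the floor and the summary and is not given as 1 value: over distinct samples it was 1.08 with normexp, 1.31 with the mean of all probes and 2.97 with total gene signal, past the threshold in each. The 2 genes are neighbours on chromosome 4 of the GRCr8 assembly (Mir141 from 159209525 to 159209618, Mir200c from 159209965 to 159210033), and both miRNAs are abundant in epithelia. miR-208, a miRNA encoded within a cardiac myosin heavy chain gene, fell by 1.34 on the log2 scale over distinct samples (limma adjusted p = 0.0194), from 11.59 ± 0.34 (SD, n = 4) to 10.25 ± 0.21 (SD, n = 3). Over 15 arrays the log2 difference was -1.44 (SE 0.24, adjusted p = 0.000531). All 3 distinct GF samples lay beyond every control sample for these 3 miRNAs, and each of the 3 passed in both fits under the scaling used here and 6 other scalings and summaries. Over distinct samples miR-200c and miR-141 also passed scaled to the hur control spots and with the authors' deposited values, while miR-208 did not (-1.33 ± 0.34 and -1.06 ± 0.29, SE, with adjusted p of 0.0574 and 0.0618).

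**Figure D1:**
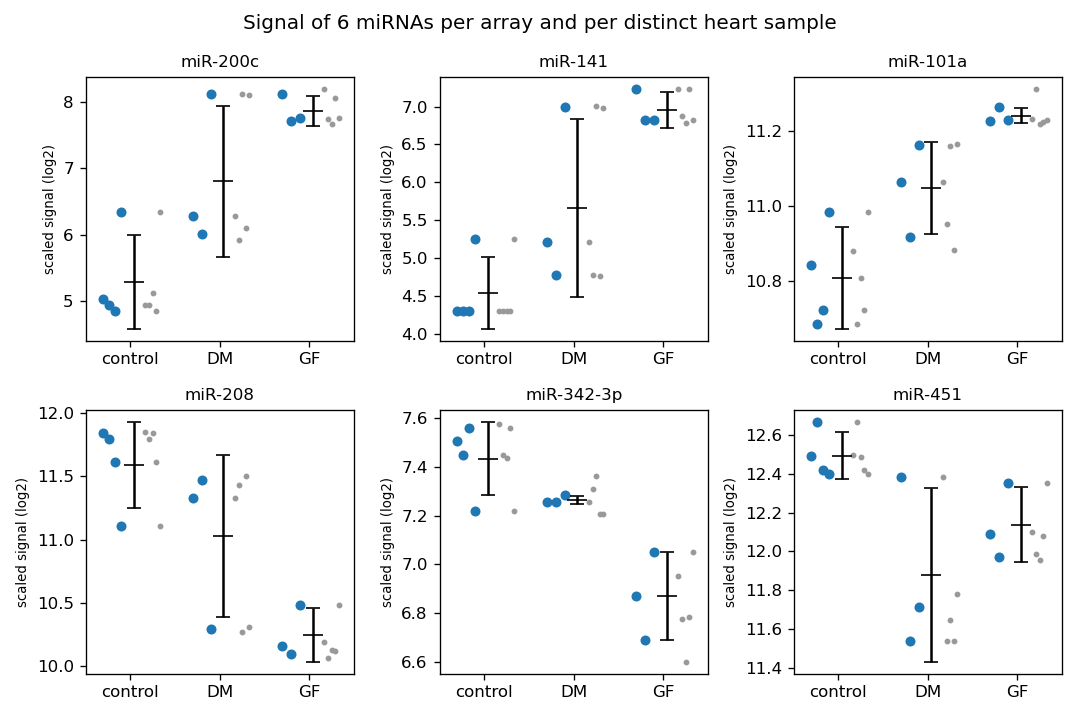
Scaled signal (log2) of 6 miRNAs in control, DM and GF hearts. Grey points are the 15 arrays, blue points the 10 distinct samples, and bars the mean and SD over distinct samples; in all 3 GF samples miR-200c, miR-141 and miR-101a lie above every control sample and miR-208 and miR-342-3p below, while DM replicates 3 and 5, counted as 1 sample, lie near the GF samples for miR-200c, miR-141 and miR-208.

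Over the 15 arrays, 60 miRNAs passed the threshold between GF and control, 21 higher and 39 lower (limma; 76 at an unadjusted p under 0.05). Over the 10 distinct samples 13 passed, 5 higher and 8 lower (51 unadjusted), and with the pairs as a random block 17 passed. With all arrays merged that lie within the range of the stated error (3 control, 2 DM and 3 GF samples), 0 passed in limma (35 unadjusted); the log2 difference of miR-200c was then 2.45 (adjusted p = 0.0762). The 13 were all among the 60. Besides miR-200c, miR-141 and miR-208, over distinct samples miR-101a rose by 0.43 (SE 0.092), miR-20a by 0.47 (SE 0.11) and miR-19b by 0.45 (SE 0.11), with adjusted p of 0.0194, 0.0367 and 0.0385. miR-181d fell by 0.63 and miR-342-3p fell by 0.57, with adjusted p of 0.0329 and 0.0194. miR-142-5p fell by 0.64, miR-22* fell by 0.56, miR-146a fell by 0.46 and miR-497 fell by 0.41 (adjusted p of 0.0367, 0.0194, 0.0194 and 0.0194). The remaining one, miR-345-5p, lay outside the naming rule and is named because the count is small; it fell by 0.33 (0.0393). For each of the 13, all 3 GF samples lay beyond every control. Their choice by p-value on these same samples makes that likely, so it is no added support. The calls depended on the scaling and summary. Of the 8 lower calls, 8 passed with normexp, 8 with the mean of all probes, 7 with total gene signal, 3 with quantile normalization, 1 (miR-208) with 75th percentile over all probes, 1 (miR-208) with no scaling, 0 scaled to the control spots and 0 with the authors' deposited values (limma). Of the 5 higher calls, 3 passed with total gene signal, where miR-20a and miR-19b had an adjusted p of 0.0646, 2 (miR-200c and miR-141) scaled to the control spots and 2 with the authors' deposited values, and 5 under each of the rest. For the 7 lower calls other than miR-208, the median log2 difference was -0.56 with a median SE of 0.11 in the scaling used here. It was -0.43 (median SE 0.15) with 75th percentile over all probes, -0.46 (0.12) with quantile normalization, -0.55 (0.17) scaled to the control spots and -0.24 (0.20) with no scaling, which moves every miRNA alike. The whole counts over distinct samples were 15 higher and 1 lower with 75th percentile over all probes, 16 and 2 with no scaling, 7 and 3 with quantile normalization, 6 and 9 with normexp, 8 and 13 with the mean of all probes and 3 and 13 with total gene signal. The count of 13 was 0 without the sample of control replicates 1 and 3, control replicate 2, control replicate 4 or the sample of GF replicates 2 and 4. It was 28 without control replicate 5, whose profile lay nearer to those of DM replicates 1, 2 and 4 (reduced chi-squares of 1.30, 2.05 and 1.77) than to any other control array (3.59 to 4.83). It was 24 without the sample of DM replicates 3 and 5, and 8 without GF replicate 6.

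The other miRNAs past the threshold in 15 arrays did not pass over distinct samples. The largest of these differences were miR-34a (log2 0.68 over distinct samples, adjusted p = 0.0745), miR-223 (0.51 over distinct samples, 0.0611), miR-92a (0.56, 0.0551) and miR-17 (0.46, 0.0611) on the higher side. On the lower side were miR-196c (-1.31 over distinct samples, 0.0551), miR-214 (-0.57, 0.0887), miR-142-3p (-0.48, 0.0887), miR-199a-5p (-0.48, 0.0887), miR-9 (-0.54, 0.0822) and miR-34b (-0.54, 0.212). The remaining named miRNAs on the higher side were miR-19a (0.38 over distinct samples, 0.0611), miR-326 (0.34, 0.161) and miR-296* (0.36, 0.216).

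**Figure D2:**
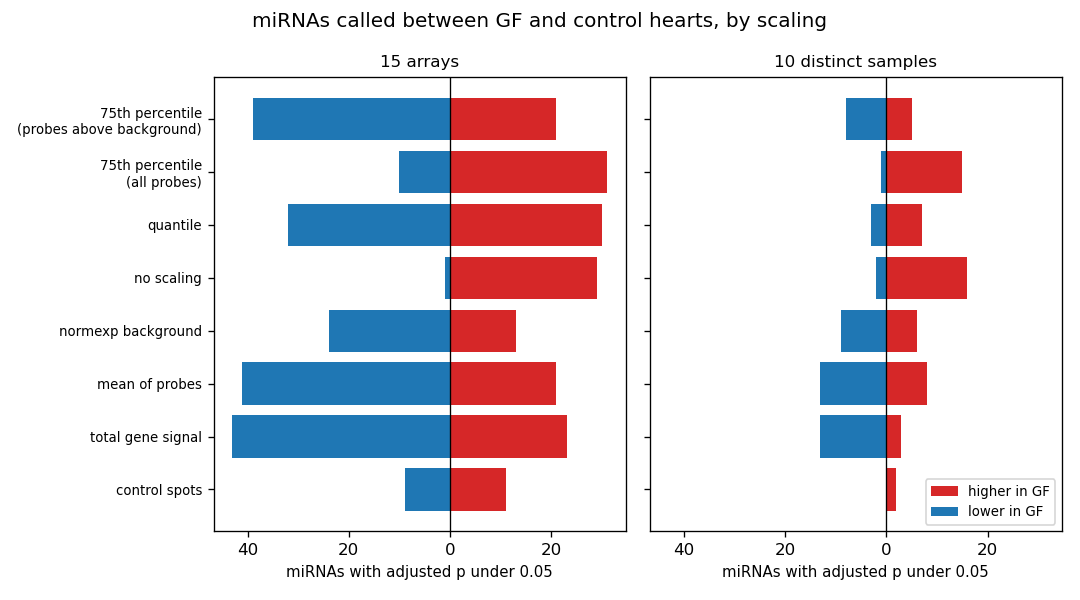
Numbers of miRNAs with an adjusted p under 0.05 between GF and control hearts, higher (red) and lower (blue), under 8 ways to scale or summarise the signal, for 15 arrays (left) and 10 distinct samples (right). With 15 arrays the lower calls number 39 in the scaling used here and 1 with no scaling.

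Lists of related miRNAs were tested as groups. In GF against control, 5 of 15 lists passed the preset-correlation test. The muscle miRNAs, made mainly in striated muscle, were lower (median log2 -0.32 over 5 members, adjusted p = 0.0375, and adjusted p = 0.412 with an estimated correlation); 4 of the 5 passed over 15 arrays, all lower, and miR-208 alone passed over distinct samples. With no scaling the median of that list was 0.022, where that of all tested miRNAs was 0.27. The miR-200 family was higher (median 1.30 over 4 members, adjusted p = 0.0375, and adjusted p = 0.412 with an estimated correlation), with 2 members past the threshold in both fits. That list was written with knowledge of the study's own report on miR-200c and miR-141, so it is not independent evidence. The miR-29 family, known for repressing collagen genes, was higher (median 0.34 over 3 members, adjusted p = 0.0375, and adjusted p = 0.412 with an estimated correlation); all 3 passed over 15 arrays and 0 over distinct samples. The miR-17-92 and paralogous clusters (median 0.39 over 9 members, adjusted p = 0.0264, and adjusted p = 0.412 with an estimated correlation) held 5 calls, all higher, of which miR-20a and miR-19b passed in both fits. The glucose and insulin-linked miRNAs (median 0.18 over 10 members, adjusted p = 0.0264, and adjusted p = 0.412 with an estimated correlation) held 4 calls, all higher, and 0 over distinct samples. The 4 were the 3 members of the miR-29 family, which this list shares, and miR-223. The glucose list and the miR-29 family are therefore not separate evidence. With an estimated correlation 0 lists passed. Over distinct samples 3 lists passed, those of the miR-200 family, the miR-17-92 clusters and glucose (0.0317, 0.0178 and 0.0317). With no scaling 1 list passed, that of glucose, and without GF replicate 1 there were 2. Adjusted over the list alone, over distinct samples, 2 members of the muscle list, 2 of the miR-200 family and 6 of the miR-17-92 and paralogous clusters passed, and 0 of the miR-29 family and the glucose list.

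The other lists did not pass in GF against control. The cardiac hypertrophy and stress list had 2 higher and 7 lower calls among 16 members (adjusted p = 0.0844, but 0.0188 with quantile normalization). The leukocyte list had 1 higher and 3 lower among 5 (0.389). The endothelial list had 2 lower calls among 3, among them miR-126 (-0.37 over distinct samples, adjusted p = 0.0542), with an adjusted list p of 0.0877. The hypoxia and oxidative stress list had 4 higher and 3 lower among 9 (0.124), and shares miR-200a, miR-200b, miR-200c and miR-141 with the miR-200 family. The miR-15 and miR-16 family had 3 lower among 5 (0.118), the fibroblast-rich list 1 higher and 3 lower among 7 (0.975), with miR-21 at 0.32 over distinct samples (adjusted p = 0.151), and the neural, liver and pancreas list 1 lower among 3 (0.848). The miR-30 family (0.848) had 1 lower call among 5 and the let-7 family (0.848) 2 lower among 8, while the cluster of miR-322 and miR-503 (0.389) had 0 calls among 5. The smooth muscle list, the red cell list and the Dlk1-Dio3 cluster had 2 tested members each and were not tested as lists; both red cell members were lower over 15 arrays (miR-451 log2 -0.40, miR-144 -0.39) and 0 over distinct samples. Adjusted over the list alone, over distinct samples, 5 hypoxia, 4 leukocyte, 3 endothelial, 3 fibroblast-rich, 3 miR-15 and miR-16 and 1 neural, liver and pancreas miRNAs passed, and 0 of each other list of this paragraph. List median, mean and test differed in sign for the fibroblast-rich list (median -0.039, mean 0.0056, test higher), the neural, liver and pancreas list (0.088, -0.068, higher) and the miR-30 family (0.011, -0.0094, higher).

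The comparison of DM with control hearts asked which miRNAs differ in diabetes with sustained high glucose. Streptozotocin, the loss of insulin and high glucose come together in DM rats and cannot be told apart here. Over the 15 arrays 3 miRNAs passed the threshold, all lower, and over the 10 distinct samples 0 passed in limma (36 and 14 at an unadjusted p under 0.05). Over 15 arrays the direction depended on the scaling and summary: 3 higher and 2 lower passed with 75th percentile over all probes, 5 and 6 with quantile normalization, 5 and 6 with the mean of all probes, 3 and 10 with total gene signal, 1 and 2 with no scaling, 0 and 1 with normexp, 3 and 2 with the authors' deposited values and 3 and 0 scaled to the hur control spots. The difference of miR-451, a miRNA of red cells, was -0.71 over 15 arrays (SE 0.14, adjusted p = 0.0175). Over distinct samples it was -0.61 (limma adjusted p = 0.468), with 12.49 ± 0.12 (SD, n = 4) in control and 11.88 ± 0.45 (SD, n = 3) in DM hearts. The difference of miR-144, its neighbour on chromosome 10, was -0.67 (adjusted p = 0.0175; 0.468 over distinct samples), and that of miR-22* was -0.42 (adjusted p = 0.0175; 0.468 over distinct samples). The miRNAs next in order did not pass: miR-185 (log2 0.48, adjusted p = 0.0531), miR-200c (1.67, 0.0531) and miR-223 (0.40, 0.0621). For miR-200c the 3 distinct DM samples read 6.28, 6.01 and 8.12, against 6.80 ± 1.15 for their mean, and for miR-141 they read 5.21, 4.77 and 6.99. The count was 25 without control replicate 5, the sample nearer to 3 of the DM arrays than to the other controls, 7 without DM replicate 1 or 4, 1 without control replicate 4 and 0 without control replicate 1, DM replicate 3 or DM replicate 5. Over distinct samples it was 2 without DM replicate 1.

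In DM against control the muscle list was lower (median -0.17, adjusted p = 0.0258) and the miR-200 family (0.74, 0.0407) and the glucose and insulin-linked list (0.16, 0.0407) were higher. With an estimated correlation their adjusted p were 0.364, 0.364 and 0.712, and over distinct samples they were 0.015, 0.0222 and 0.104. No single member of these lists passed (0 of 5, 0 of 4 and 0 of 10). The other 12 lists had adjusted p from 0.125 to 0.951. With quantile normalization 0 of these 3 lists passed, and without DM replicate 1 there were 0. Both members of the red cell list passed over 15 arrays and, adjusted over the list alone, over distinct samples, where 0 members of any other list did. Median and mean differed in sign for the stress list (median 0.020, mean -0.025, test higher) and the fibroblast-rich list (median -0.076, mean 0.071, test lower).

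The comparison of GF with DM hearts addressed the question in the series title. Over the 15 arrays 6 miRNAs passed, all lower in GF, and over distinct samples 0 passed in limma (46 and 18 at an unadjusted p under 0.05). They were miR-142-5p (log2 -0.51, adjusted p = 0.0488), miR-181d (-0.45, 0.0249), miR-342-3p (-0.44, 0.0121), miR-146a (-0.36, 0.0135), miR-378 (-0.34, 0.0121) and miR-497 (-0.28, 0.0135), with adjusted p over distinct samples from 0.272 to 0.408. The direction depended on the scaling here too: over 15 arrays 6 higher and 5 lower passed with quantile normalization, 7 and 0 with no scaling, 4 and 0 with the authors' deposited values, 0 and 11 with normexp, 0 and 6 with the mean of all probes and 0 and 4 with total gene signal. With 75th percentile over all probes 0 passed in limma, as scaled to the hur control spots (37 and 40 unadjusted). With no scaling, where the median of all tested miRNAs moved from -0.082 to 0.29, 3 of the 6 (miR-146a, miR-378 and miR-497) lay above 0. The differences of miR-200c (0.98, adjusted p = 0.153), miR-141 (1.24, 0.0878) and miR-208 (-0.77, 0.0878) did not pass. The cardiac hypertrophy and stress list was lower (median -0.23 over 16 members, adjusted p = 0.0138) and the miR-17-92 and paralogous clusters higher (0.13 over 9 members, 0.00119), while 0 single members of either passed. With an estimated correlation both had an adjusted p of 0.532, and the median of the first was 0.15 with no scaling, where that of all tested miRNAs was 0.29. Over distinct samples, at the preset correlation, camera gave the stress list an adjusted p of 0.0196 and the miR-17-92 clusters 0.000237. Adjusted over the list alone, 12 members of the stress list passed over 15 arrays and 0 over distinct samples, where 3 leukocyte and 1 miR-15 and miR-16 miRNAs and 0 of any other list did. The other 13 lists had adjusted p from 0.0714 to 0.927. Among them the miR-29 family had 0.0714, but 0.0167 with 75th percentile over all probes. Signs differed for the let-7 family (median -0.015, mean -0.023, test higher), the neural, liver and pancreas list (0.0034, -0.092, higher) and the fibroblast-rich list (0.12, -0.066, higher). The count of 6 was 2 without DM replicate 2 or GF replicate 4, 10 without DM replicate 1 and 12 without DM replicate 5; over distinct samples it was 6 without the sample of DM replicates 3 and 5. The test of any difference among the 3 groups called 46 miRNAs over 15 arrays and 0 over distinct samples in limma (72 and 38 at an unadjusted p under 0.05).

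Slide was tested as a term because the arrays lay on 2 slides, with each group on both. On both slides the positions followed the group, with controls first, DM next and GF last. No GF array shared a position with a control or DM array. Position therefore cannot be told apart from group in the comparisons with GF, and a slide term does not remove it. With slide as a block, 3, 57 and 5 miRNAs passed in DM minus control, GF minus control and GF minus DM. Within slide 1 limma called 0, 0 and 0 (16, 40 and 8 unadjusted) and within slide 2 it called 2, 0 and 0 (12, 50 and 10 unadjusted), with 2 or 3 arrays per group. The GF minus control difference of miR-200c was 3.03 within slide 1 and 2.40 within slide 2, and that of miR-208 was -1.69 and -1.27.

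DM and GF differences were both taken against the same controls, which links them. Across the 165 miRNAs their Pearson r was 0.875 and Spearman rho 0.821 over 15 arrays, where miRNAs are not independent replicates. Over distinct samples r was 0.858, and simulated unchanged groups with shared controls gave a mean r of 0.414 and at most 0.75. With the controls split so that each difference had its own, r ran from 0.602 to 0.749 over 6 splits of the distinct samples, with a median of 0.682. Over 20 splits of the arrays it ran from 0.577 to 0.83, but control replicates 1 and 3, counted as 1 sample, can lie on both sides of these. All 3 miRNAs lower in DM were also lower in GF over 15 arrays; the shared controls link these calls too.

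The authors' deposited table of the 3-group test lists 35 miRNAs, and the same 35 were recomputed here from the deposited log2 values without correction for multiple tests; 4 pass after Benjamini-Hochberg adjustment (miR-141, miR-200c, miR-296* and miR-29b). The authors' deposited table of DM against control lists 5 miRNAs, of which 2 (miR-451 and miR-144) were called here over 15 arrays, and miR-200c, miR-141 and miR-184 were not. The authors' deposited table of GF against control lists 30 miRNAs, 29 higher and 1 lower. Of these, 19 were called here over 15 arrays with the same sign. The same fit called 41 that are not in it, among them miR-342-3p, miR-497, miR-181d and miR-22*. Among the 11 of that table not called over 15 arrays were miR-185, let-7e, miR-301a and miR-324-5p. Of the miRNAs called over distinct samples, miR-200c, miR-141, miR-208, miR-101a and miR-20a are in that table and the others are not. The authors' deposited table of GF against DM lists 20 miRNAs, all higher, among them miR-141, miR-150, miR-101a and miR-136. Of these, 0 were called here, and the 6 called over 15 arrays are not in it. Over distinct samples 0 were called in limma. Those deposited values carry no scaling between arrays. No miRNA (0) was at background on every array of 1 group and above it on all 5 of another.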

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

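All tests weighed in this part were chosen after the result was seen. The test for a sample far from the others of its group was run on the distinct samples, which were defined after the data were seen. That test covered 57 sets of values of the 4 distinct control samples, for 53 named miRNAs and 4 array measures; DM and GF, with 3 samples each, were not tested. It picked out 8, where chance gives about 1 in 20 groups, and 7 of the 8 were control replicate 5. The 57 sets come from the same 4 samples and are not independent, so that rate does not test the 8 together. For miR-141 the outcome was set by the floor, since the other 3 controls lie on it, so that this value counts for nothing against chance. For control replicate 5, miR-200c read 6.34 on the log2 scale, against 4.84 to 5.03 in the other controls. In the same sample miR-141 read 5.25 with the others at the floor of 4.31, and miR-34a read 11.003, against 10.25 to 10.37. Its miR-199a-5p read 9.53 (others 9.15 to 9.20), miR-19a 7.75 (7.44 to 7.49) and miR-19b 10.53 (10.34 to 10.37). Its miR-196c was the lowest of the controls at 5.68 (6.67 to 6.83). For control replicate 4, miR-22* read 8.68, against 8.39 to 8.43.

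For 5 of the 7 miRNAs, control replicate 5 lay within the range of the DM samples, and for 1 within that of the GF samples. Over all 156 miRNAs compared, control replicate 5 had a reduced chi-square of 1.30 with DM replicate 1, the lowest of any pair of arrays from different groups, 1.77 with DM replicate 4 and 2.05 with DM replicate 2. With GF replicates 5 and 1 it was 2.71 and 3.43, with the other controls 3.59 to 4.83, and with DM replicates 3 and 5 it was 6.60 and 6.09. Control replicate 5 and DM replicate 1 lay at the same position on different slides. So did 3 of the 5 close pairs. These comparisons were chosen after the values were seen, and no explanation was tested. The 75th percentile of the signal of control replicate 5, 2282, lay within that of the other control arrays, 1774 to 2441. Without this sample the count over 15 arrays was 25 for DM against control, and the counts over distinct samples were 28 for GF against control and 13 for any difference among the 3 groups.

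miR-200c and miR-141 were higher in GF than in control hearts. Array brightness as the whole cause is argued against for miR-200c by the scalings: the lowest log2 difference of miR-200c over distinct samples was 1.43, past the threshold, with the normexp background correction. Slide is argued against for miR-200c as well, since the lower of its within-slide differences was 2.40. Both are argued against for miR-141 too, although 3 of the 4 distinct controls lie at the floor. The floor can only make the difference smaller, but it gives these 3 controls 1 value, which narrows their spread and can lower the p-value. For miR-141 the lowest log2 difference over the same scalings was 1.08, with normexp, where no floor was set, and past the threshold. Within each slide its lowest GF array lay above the highest control array by at least 1.53. RNA from epithelial cells may contribute and stays open: 0 of 6 other epithelial miRNAs (miR-182, miR-183, miR-96, miR-203, miR-205 and miR-375) were well above background on 3 or more GF arrays, but no sample here shows that their probes report these miRNAs. The treatment, which the design names, also stays open, as does position on the slide, which went with the group. Neither was tested apart from these.

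5 pairs of arrays differed by less than the stated measurement error. Position on the slide as the whole cause is argued against: of 7 pairs of arrays at 1 position across the slides, 4 had a reduced chi-square over 1. Of the 5 close pairs, 3 lay at 1 position and 2 at 2 positions, while only 7 of all 105 array pairs share a position. For those 3, position and the same RNA on both slides cannot be told apart. The same RNA hybridized on both slides is a candidate explanation: all 5 close pairs lay across slides within a group, where 17.1% of all array pairs lie. That share takes in pairs of different groups. Of the same-group pairs, more lay across slides (18) than within a slide, so the crossing of slides alone is weak support. The labels do not name shared RNA, and no biological explanation was tested.

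The signal before scaling was higher on GF than on control arrays. The bright corner spots were lower on GF arrays by a log2 difference of -0.46, which goes against scanner gain or a dye effect on every spot. Position on the slide went with the group, so such an effect offset by position is not excluded. A brighter array (labelling, RNA amount or hybridization) may account for the higher signal: the hur control spots read 12.43 ± 0.30 (SD, n = 3) in GF and 12.13 ± 0.35 (SD, n = 4) in control samples on the log2 scale. That difference of 0.30 did not pass (two-sided exact permutation p = 0.286; the smallest possible is 0.0286), and lies within the spread of the samples, so it neither supports nor excludes a brighter array. A general rise of miRNAs in GF hearts, with a median difference of 0.25 with no scaling, cannot be told apart from it, because what the hur spots report is not given in the sources used here.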

How the results depend on the processing

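The distinct samples, the pairs of arrays as a random block, the merging of arrays within the error range, the scaling to control spots and every alternative run on distinct samples were chosen after the data were seen; the rest was planned. Of the values of named miRNAs under the alternatives fixed beforehand that keep all replicates or 1 slide, 535 of 711 for GF against control kept direction and side of the threshold, 9 gained a call, 18 reversed and the rest lost the call. For DM against control 274 of 318 kept both, 15 lost the call, 28 gained it and 1 reversed; for GF against DM the numbers were 281 of 348, 40, 10 and 17. With 1 replicate left out, 622 of 675, 274 of 300 and 303 of 330 kept both and 0 reversed. Values of miRNAs that were not called and stayed so count as kept in all of these. Of the named miRNAs, only 3 of 20 were called in DM against control and 6 of 22 in GF against DM over 15 arrays. The shares kept therefore say little about how stable the calls are. No spot was saturated (0), and signal over background limits what could be tested: 185 of 350 miRNAs were too near background to test. Replicate numbers were not taken to pair the samples, because 6 of 13 pairs that share a number, not all, had deviations from the group means that correlated above 0.1 (-0.528 to 0.474). Their median was 0.060, against -0.033 for other pairs, and 7 of 15 arrays matched best an array of their own number, a hint from the data that the labels do not explain. With replicate number as a block, the replicate block gave 4, 50 and 1 miRNAs in DM against control, GF against control and GF against DM. Unless stated otherwise, the cause of a change below was not tested.

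The count of 60 for GF against control stayed within 1.5-fold under 75th percentile over all probes, quantile normalization, mean of all probes, total gene signal, both filters, slide as a block, the replicate block, only the 2 groups compared, and trend and robust variance (41 to 66). It was 30 with no scaling, 37 with normexp, 35 with the authors' deposited values, 20 scaled to control spots, 13 over distinct samples, 17 with the pairs as a random block and 32 with the authors' kind of test after Benjamini-Hochberg. Of the 30 with no scaling 29 were higher, where 21 of the 60 were, since the removal of the scaling factor moves every miRNA alike. Of the 60, 22 were among the 30. Within slide 1 and within slide 2 it was 0 in limma (40 and 50 unadjusted), which the smaller number of arrays brings with it at least in part. With all arrays within the error range merged (3 control, 2 DM and 3 GF samples), the counts for DM against control, GF against control, GF against DM and any difference were 0, 0, 0 and 0 in limma (7, 35, 7 and 23 unadjusted), where fewer samples are left. Over distinct samples the count of 13 became 21 with the mean of all probes, 2 with the authors' deposited values and 2 scaled to control spots.

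The count of 3 for DM against control was 5 with 75th percentile over all probes, 11 with quantile normalization, 1 with normexp, 11 with the mean of all probes, 13 with total gene signal and 5 with the authors' deposited values. It was 0 with no filter on dim probes (38 unadjusted; more miRNAs were tested), 7 with probes above background on all arrays, 0 with only the 2 groups compared (35 unadjusted), 8 with trend and robust variance, 0 within slide 1 (16 unadjusted), 0 over distinct samples (14 unadjusted) and 0 with the pairs as a random block (16 unadjusted). The authors' kind of test gave 30 unadjusted and 0 adjusted.

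The count of 6 for GF against DM was 0 with 75th percentile over all probes (37 unadjusted), 11 with quantile normalization, 11 with normexp and 1 with the replicate block. It was 0 within slide 1 (8 unadjusted), 0 within slide 2 (10 unadjusted), 0 over distinct samples (18 unadjusted), 0 with the pairs as a random block (21 unadjusted) and 0 scaled to control spots (40 unadjusted). With no scaling it was 7, all higher, and 0 of the 6 were among them. The authors' kind of test gave 33 unadjusted and 0 adjusted. Over distinct samples the count of 0 became 1 with no scaling and 1 with normexp.

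The count of 46 for any difference among the 3 groups was 29 with 75th percentile over all probes, 22 with no scaling, 27 with the authors' deposited values, 28 with no filter, 15 with the pairs as a random block, 19 scaled to control spots and 20 with the authors' kind of test after adjustment. It was 0 over distinct samples (38 unadjusted), 0 within slide 1 (26 unadjusted) and 0 within slide 2 (29 unadjusted). Over distinct samples the count of 0 became 3 with 75th percentile over all probes, 1 with quantile normalization, 2 with no scaling, 3 with the mean of all probes, 2 with the authors' deposited values and 2 scaled to control spots.

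With 1 replicate left out, the counts ran from 0 to 25 for DM against control, 43 to 68 for GF against control, 2 to 12 for GF against DM and 26 to 63 for any difference. Any difference gave 27 without control replicate 1, 30 without control replicate 3, 26 without control replicate 4 and 27 without GF replicate 4. With 1 distinct sample left out they ran from 0 to 2, 0 to 28, 0 to 6 and 0 to 13; any difference gave 13 without control replicate 5, 12 without the sample of DM replicates 3 and 5 and 2 without DM replicate 1. The correlation of the DM and GF differences ran from 0.805 to 0.907 with 1 replicate left out, and its median was 0.765 with the control arrays split into sets of 2 and 3, where control replicates 1 and 3 can lie on both sides. Over 6 splits of the distinct controls, which share none, it was 0.682.

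Reversed log2 differences with no scaling, for GF against control, were those of miR-133a (0.015), miR-30e (0.20), let-7c (0.12), let-7b (0.13), miR-195 (0.079), miR-126* (0.052) and miR-503 (0.032). For GF against DM they were miR-146a (0.013), miR-378 (0.038), miR-497 (0.092), miR-30e (0.25), let-7i (0.27), miR-27b (0.18), miR-221 (0.0068) and miR-33 (0.17). The median over tested miRNAs moved from -0.052 to 0.27 and from -0.082 to 0.29, as the removal of the scaling factor must move every value. The authors' deposited values, which are not scaled either, reversed miR-133a (0.0052), miR-30e (0.23), let-7c (0.11), let-7b (0.099), miR-195 (0.061) and miR-126* (0.053) for GF against control. For GF against DM they reversed miR-378 (0.036), miR-497 (0.077), miR-30e (0.26), let-7i (0.26), miR-27b (0.18) and miR-33 (0.15). With normexp, miR-136 reversed in DM against control (0.18), miR-296* (-0.051), miR-145 (-0.075) and miR-136 (-0.11) in GF against control, and miR-145 (-0.27), miR-136 (-0.29) and miR-450a (-0.14) in GF against DM. Within slide 1, miR-494 (0.16) and miR-503 (0.11) reversed in GF against control.

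The number of lists called, 3, 5 and 2 for DM against control, GF against control and GF against DM, was 0, 0 and 0 with an estimated correlation and 1, 9 and 1 with fry, which does not compare a list with other miRNAs. It was 0 for DM against control with quantile normalization and 1 with the mean of all probes; 1 for GF against control with no scaling, 8 with no filter and 3 over distinct samples; and 1 for GF against DM with no scaling and 4 with no filter. With 1 replicate left out these ran from 0 to 3, 2 to 5 and 2 to 4. The count was 1 without control replicate 1 and 0 without DM replicate 1 for DM against control, 2 without GF replicate 1 for GF against control and 4 without GF replicate 4 for GF against DM.

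Lists of DM against control lost their call as follows, by adjusted p. The muscle list had 0.319 with quantile normalization, 0.364 with an estimated correlation and 0.0505 with fry, and 0.00516 to 0.0832 with 1 replicate left out. The miR-200 family had 0.0553 with quantile normalization, 0.0692 with the mean of all probes and 0.364 with an estimated correlation, and 0.0202 to 0.0832 with 1 replicate left out. The glucose list had 0.105 with quantile normalization, 0.0848 with no scaling, 0.0692 with the mean of all probes, 0.104 over distinct samples, 0.712 with an estimated correlation and 0.182 with fry, and 0.015 to 0.0832 with 1 replicate left out.

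In GF against control the estimated correlation gave each of the 5 lists 0.412. The muscle list had 0.152 with quantile normalization, 0.0754 with no scaling and 0.059 over distinct samples, and 0.0214 to 0.061 with 1 replicate left out. The miR-200 family had 0.0772 with 75th percentile over all probes, 0.0777 with quantile normalization and 0.0878 with no scaling, and 0.0214 to 0.0596 with 1 replicate left out. The miR-29 family had 0.0754 with no scaling and 0.059 over distinct samples, and 0.0307 to 0.0596 with 1 replicate left out. The miR-17-92 clusters had 0.0754 with no scaling and 0.00401 to 0.0381 with 1 replicate left out, and the glucose list 0.0538 with fry and 0.0174 to 0.0494 with 1 replicate left out. In GF against DM the estimated correlation gave both lists 0.532; the miR-17-92 clusters had 0.113 with no scaling and 0.276 with fry, and 2.18e-05 to 0.0286 with 1 replicate left out. The stress list ran from 0.00954 to 0.033.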

Other observations

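In this part the splits of the 15 arrays were planned; the splits of the distinct samples, which were defined after the data were seen, were added later, and the other values were picked after they were seen. DM samples differed among themselves. For miR-200c, the sample of DM replicates 3 and 5 read 8.12 on the log2 scale, DM replicate 1 read 6.28 and the sample of DM replicates 2 and 4 read 6.01, while the GF samples read 8.13, 7.71 and 7.76. For miR-208 the same DM samples read 10.29, 11.32 and 11.47, with a GF mean of 10.25 ± 0.21 (SD, n = 3). For miR-451 they read 11.72, 12.38 and 11.54, and the controls 12.49, 12.66, 12.42 and 12.40.

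The other members of the miR-200 family were near background. miR-200a was well above background on 1 control, 3 DM and 3 GF arrays and miR-200b on 1, 3 and 2, while miR-429, whose gene lies with theirs on chromosome 5, was so on 0 arrays. Of the tested miRNAs, miR-184 and miR-18a were above background on no array (0) of at least 1 group.

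Other splits of the same samples were fitted in the same way. Splits of the 15 arrays exchange the arrays of the 5 close pairs as if they were separate samples, so a small share of them excludes chance only as far as that holds, and the distinct samples decide below. For the 60 miRNAs between GF and control over 15 arrays, 1 of 100 splits, the real one, gave as many, and the highest of the others gave 42, with control replicate 5 and GF replicate 6 exchanged. Over distinct samples 2 of 35 splits gave at least the real 13, the other giving 28 with control replicate 5 on the GF side, so chance is not excluded. For the 5 lists between GF and control, 2 of 100 splits of the arrays gave as many (highest other 5), while over distinct samples 10 of 35 gave at least the real 3 (highest other 5), so chance is not excluded.

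For DM against control, 7 of 100 splits gave at least the 3 miRNAs called (highest other 14), so chance is not excluded; for the 3 lists 4 of 100 did (highest other 4). Over distinct samples the real count of miRNAs was 0, which any split must reach (highest other 10), so that count decides nothing. There 6 of 35 splits gave at least the real 2 lists (highest other 4), so chance is not excluded for the lists either. For GF against DM, 3 of 100 splits of the arrays gave at least 6 miRNAs. The highest other, 40, set DM replicates 1, 2 and 4 with GF replicates 1 and 5 against the rest, which points to a structure of the samples. For the 2 lists 34 of 100 splits gave as many (highest other 4), so chance is not excluded. The distinct DM and GF samples allow 10 splits, too few for a share under 0.05; the real count of miRNAs was 0 and the highest other 2, from the split that gave 40 over the arrays, and the real count of lists was 2 and the highest other 3. For any difference among the 3 groups, 1 of 100 splits of the arrays, the real one, gave 46 miRNAs (highest other 24). Over distinct samples the real count was 0 (highest other 9), which any split must reach. Those splits therefore cannot decide, and chance stays open.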
